A study of Mus musculus with 16 samples.

How the data were processed

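H3K4me3 ChIP-seq was done on whole testis at 13 days post-partum, per the labels, in B6 (C57BL/6JOlaHsd), B6-TgWT and B6-TgYF mice. The name of the deposited B6 list carries a d followed by 12, where the labels of its samples give 13 days. The age in the labels was used, and which of them holds for the B6 list is not settled here. Samples were grouped by the antibody and line in the labels. The authors deposited 1 peak list per line, named in the labels of both ChIP libraries and of the input. The submitters' processing notes name CASAVA, Bowtie2, BWA and MACS2 and the build mm9, with no role or version. How the replicates were combined and which cutoff was used are not given in the sources used here.

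Each list had 10 columns without a header and was read in the usual order of MACS peak files. The deposited fold enrichment is a ratio to background at the peak, as the authors' caller gave it. The deposited score of each peak was 10 times its −log10 p, truncated to a whole number, in every row. The −log10 p and −log10 q of each peak are the authors' values too, and all these values were used to describe, rank or filter the peaks of a list. In places, fold enrichments of separate lists are set side by side, which shows no change by itself. In the authors' deposited table for each line, the lowest −log10 p was 11 in B6, 12 in B6-TgWT and 11 in B6-TgYF. The highest number in the peak names was 90822, 112488 and 99491, above the number of peaks listed. Coordinates are those of the lists, counted from 1.

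Peaks on chromosomes 1 to 19 and X were used. Peaks sharing at least 1 bp were joined into regions and sorted into 7 classes by the lists that contributed. A peak was called absent from a list when that list held no peak overlapping it, which does not show that the mark was missing. Shares have 95% Wilson intervals, and chance levels come from 100 circular shifts of the other list within each chromosome. The chance level for peaks absent from B6 was added after the data were seen. Strength was the percentile of fold enrichment within the list, and deciles were made from it. No test was run across replicates, since no list holds values per replicate. The region sorting was tested on simulated data, where all 7 classes over 60491 sites were recovered in 100% of cases under 4 overlap rules. The simulated sites were spaced so that different sites never touched. This checked the code only, and cannot tell how well real neighbouring peaks were sorted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

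Named regions were the 10 strongest of the B6-TgWT list alone and the 5 strongest of every other class, by fold enrichment or, in several lists, by the mean percentile. This rule and the counts and shares of the comparisons were fixed before the data were examined. The rank correlations, the counts expected under independent losses, the ratios between counts and the stretches without peaks were not part of that plan. Alternatives were other overlap rules, the strongest 50% of each list or of the list asked about, lists of equal length, all chromosomes and −log10 q as the measure of strength. A common lowest −log10 p of 12 and leaving out the start of chromosome 11 were added after the data were seen.

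A genome or annotation of mm9 was not used here. The gene table at hand was of GRCm38, where the last gene of chromosome 1 ended at 195.291 Mb, while the last peak of that chromosome over the 3 lists ended at 197.134 Mb. So no peak was assigned to a gene, promoter, exon or intron, and the gene lists, promoter shares and sequence motifs set out beforehand were not computed. Promoters and PRDM9 sites were therefore not separated in any class. The DMC1 libraries and the inputs' own coverage were not analysed here.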

Results

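The series profiled H3K4me3, the histone mark of active promoters, in testes of mice aged 13 days post-partum. PRDM9 is a meiotic histone methyltransferase that places the same mark at the sites its zinc fingers bind, and these sites become recombination hotspots. The series title asks whether this methyltransferase activity is needed for meiotic DNA double-strand breaks. From what is known of the study, the WT transgene supplies an active PRDM9 of another binding specificity and the YF transgene a form mutated in the catalytic domain. Of 16 samples, 6 were H3K4me3 ChIP libraries, 3 were inputs and 7 were DMC1 ChIP libraries, which mark break sites and were not analysed here. B6 mice without a transgene, B6-TgWT mice and B6-TgYF mice each had 2 H3K4me3 libraries and 1 input. The labels give a different C57BL/6 substrain for each line, so a difference between lists is a difference between lines, not of the transgene alone. The name of the B6 list carries the number 12 where its labels, like those of both transgenic lines, give 13 days.

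Each line had 1 peak list, so no difference below could be set against a spread between replicates. The 95% Wilson intervals cover counting error over peaks only, and peaks are not replicates. On the autosomes and X, the B6 list held 51170 peaks, the B6-TgWT list 47648 and the B6-TgYF list 42496. Their median widths were 1111, 1214 and 1172 bp. The authors' fold enrichment over background had medians of 7.74, 6.83 and 7.59. Read depth behind the lists is unknown, as they hold no read counts.

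The first comparison asks which H3K4me3 regions the 3 lines shared. Merging overlapping peaks gave 60491 regions, of which 35780 (59.1%, interval 58.8 to 59.5) had a peak in all 3 lists. Their fold enrichment ranked alike in each pair of lists, with Spearman's rho across regions of 0.896 for B6 and B6-TgWT, 0.915 for B6 and B6-TgYF, and 0.909 for the transgenic pair. Regions are not independent replicates, and no p-value was computed. The region ranked first over all 3 lists lay on chromosome 15 at 81876247 to 81878906 (mm9), with fold enrichments of 39.41 in B6, 35.88 in B6-TgWT and 38.03 in B6-TgYF. The next ones lay on chromosome 4 at 94222234 to 94224380, chromosome 14 at 122503387 to 122507846, chromosome 7 at 129209372 to 129212125 and chromosome 5 at 28642681 to 28645060.

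**Figure D1:**
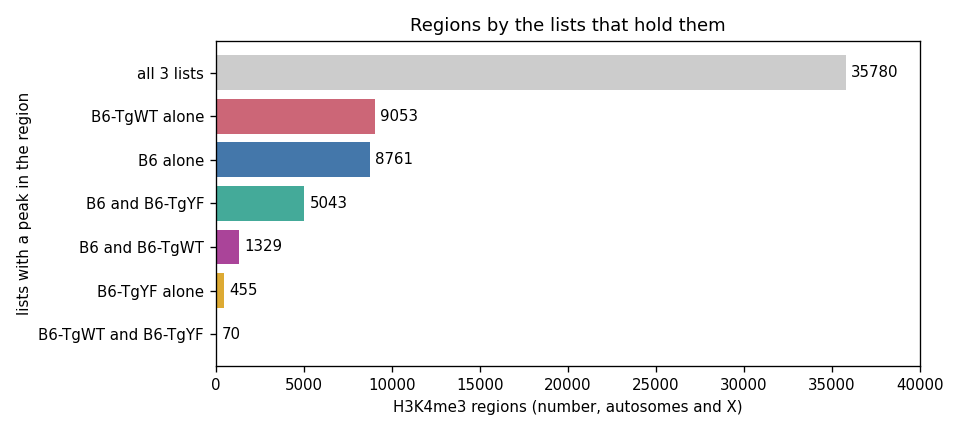
Number of H3K4me3 regions on the autosomes and X (x axis) for each combination of lists with a peak in the region (y axis), 1 bar per combination and 1 list per line. The B6-TgWT list alone held 9053 regions, the B6-TgYF list alone 455.

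The second comparison asks which H3K4me3 sites came with the WT transgene and whether they were also present with the YF transgene. In the B6-TgWT line, 9123 regions had a peak where the B6 list had none, against 525 in the B6-TgYF line, a ratio of 17.4. Of the B6-TgWT peaks, 9126 (19.2%, interval 18.8 to 19.5) overlapped no B6 peak. The B6-TgYF list overlapped 73 of these 9126, or 0.80% (interval 0.637 to 1.005). Shifting the whole B6-TgYF list along the chromosomes gave 4.29% on average, and shifting only its peaks absent from B6 gave 0.0385%, at most 0.0877%. The whole list is no fair reference, as 98.8% of its peaks overlapped B6 and the 9126 were chosen to lack B6 peaks. So the 4.29% shows no depletion, and the 0.80% lay above the second chance level. In the B6-TgYF list, 530 peaks (1.25%, interval 1.15 to 1.36) overlapped no B6 peak, and 75 of them (14.2%, interval 11.4 to 17.4) overlapped a B6-TgWT peak. The chance levels for this share were 3.68% on average with the whole B6-TgWT list shifted and 0.709%, at most 1.51%, with only its peaks absent from B6. Here too the second level is the one to compare. With equal list lengths, which shorten the B6 list, the B6-TgYF regions absent from B6 numbered 3050 and the B6-TgWT ones 8523. The share of B6-TgWT peaks absent from B6 that the B6-TgYF list overlapped was 9.335% with only the strongest 50% of each list kept, 8.0755% with equal lengths and 8.26% when summits within 500 bp were matched, a rule under which 1861 B6-TgYF regions were absent from B6. Under these settings a peak counted as absent from B6 could still overlap a peak of the full B6 list. Among the stronger 50% of peaks, 2395 of B6-TgWT and 1 of B6-TgYF overlapped nothing in the full B6 list. The B6-TgYF list overlapped 0.4175% of those 2395.

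Regions held by the B6-TgWT list alone included strong peaks. Of their 9053 peaks, 2385 (26.3%, interval 25.4 to 27.3) lay in the stronger 50% of that list. Their median fold enrichment was 5.19 and the highest 19.45. By contrast, 0 of the 455 peaks held by the B6-TgYF list alone and 0 of the 8761 held by the B6 list alone lay in the stronger 50% of their lists. Within the B6-TgWT list, peaks of that list alone made up 29.0% of the weakest decile of fold enrichment, 25.2% of decile 6, 19.9% of decile 7 and 4.43% of decile 8. Decile 9 had 11 such peaks and decile 10 had 0. Their median width was 1193 bp, against 596 bp for B6 alone and 520 bp for B6-TgYF alone. These classes also differed in strength, with median percentiles of 33.3, 12.9 and 7.66, and widths were not compared at matched strength.

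**Figure D2:**
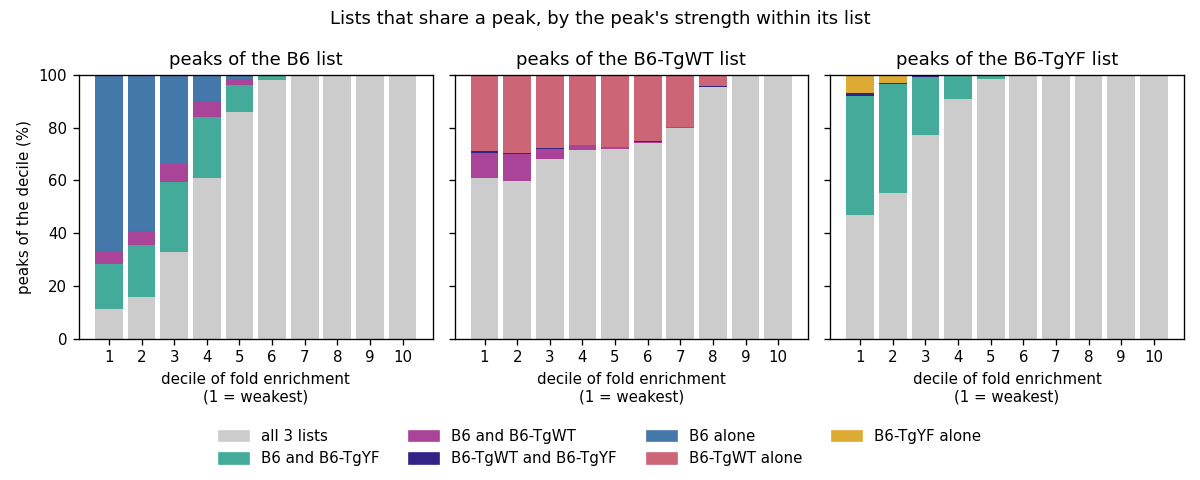
Share of peaks in percent (y axis) by the other lists that hold a peak there, in deciles of the authors' fold enrichment within each list (x axis, 1 is the weakest), 1 panel per list. Peaks of the B6-TgWT list alone made up 25.2% of its decile 6, while no peak of the B6 list alone lay above decile 5 and none of the B6-TgYF list alone above decile 4.

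The strongest region of the B6-TgWT list alone lay on chromosome 7 at 116990118 to 116991284, with a fold enrichment of 19.45. The next lay on chromosome 2 at 110012938 to 110014650 (fold 19.29), on chromosome 4 at 140110938 to 140113990 (fold 17.85) and on chromosome 17 at 46066458 to 46069344 (fold 17.73). The other 6 of the 10 named regions were on chromosome 4 at 151123980 to 151126668, chromosome 11 at 116043113 to 116045665 and 112934855 to 112936729, chromosome 17 at 45944872 to 45947423, chromosome 14 at 34702174 to 34704685 and chromosome 8 at 11239488 to 11242796. Their fold enrichments ran from 17.7 down to 17.03. The strongest regions of the B6-TgYF list alone were weaker. The first lay on chromosome 5 at 21908177 to 21908891 (fold 6.04), followed by chromosome 10 at 63513443 to 63513904 (fold 5.03), chromosome 9 at 119570124 to 119571020 (fold 4.91), chromosome 5 at 125283402 to 125284476 (fold 4.9) and chromosome 3 at 103242752 to 103243220 (fold 4.88).

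Both transgenic lists, without B6, held 70 regions, mostly weak, with median percentiles of 13.2 in the B6-TgWT list and 8.77 in the B6-TgYF list. The count was 771 when summits within 500 bp were matched, 680 with equal list lengths and 302 with the strongest 50% of each list, and it was 9 with the strongest 50% of the list asked about against the others in full. The settings with 771, 680 and 302 drop B6 peaks or ask for close summits. Their regions can therefore overlap a peak of the full B6 list, and the larger counts are not more sites missing from B6. The strongest of the 70 was on chromosome 6 at 60778189 to 60779910, with fold enrichments of 13.8 in B6-TgWT and 22.32 in B6-TgYF. It lay in a stretch of 1200.286 kb without B6 peaks. There the transgenic lists had peaks only from 60778189 to 60944981, so most of the stretch lacked peaks in all 3 lists. In the others of the 5 named, the fold enrichment was higher in B6-TgWT than in B6-TgYF, although folds of separate lists show no change by themselves. These lay on chromosome 6 at 51003226 to 51005187 (11.36 and 5.35) and on chromosome 8 at 86703648 to 86705225 (12.87 and 5.04), 34547572 to 34548807 (7.43 and 4.71) and 87239451 to 87241695 (12.65 and 3.43).

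The third comparison asks whether sites of the B6 line were missing from the lists of lines with a transgene. The B6-TgWT list overlapped 72.9% of the B6 peaks (interval 72.5 to 73.3) and the B6-TgYF list 80.2% (interval 79.9 to 80.6), with chance levels of 4.94% and 4.43%. Peaks missing from both numbered 8761, or 17.1% (interval 16.8 to 17.5). Independent losses would give 2741, or 7271 when computed within deciles of B6 strength. With equal list lengths, 8.19% of the B6 peaks were missing from both. Missing peaks were mostly weak. In the weakest decile, 83.9% were absent from B6-TgWT and 71.9% from B6-TgYF, while among the 25579 stronger peaks 101 were absent from B6-TgWT, 13 from B6-TgYF and 0 from both.

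Regions shared by B6 and B6-TgYF but not B6-TgWT numbered 5043, and those shared by B6 and B6-TgWT but not B6-TgYF 1329, a ratio of 3.79. The ratio was 1.18 when the strongest 50% of each list was kept and 11.3 with equal list lengths. The strongest of the 5043 lay on chromosome 10 at 122238848 to 122240499, with fold enrichments of 13.14 in B6 and 12.87 in B6-TgYF. It was followed by chromosome 5 at 137311946 to 137312924, chromosome 10 at 121965210 to 121965876, chromosome 6 at 34201987 to 34203178 and chromosome 12 at 112522738 to 112523405. Of the 1329, the first was on chromosome 18 at 32179750 to 32180237, with fold enrichments of 10.2 in B6 and 6.69 in B6-TgWT. The next were on chromosome 10 at 61295212 to 61298015, chromosome 3 at 129638388 to 129639245, chromosome 11 at 78797028 to 78799225 and chromosome 5 at 105227775 to 105228639. The strongest regions of the B6 list alone were on chromosome 10 at 67694209 to 67694959 (fold 7.72), chromosome 7 at 82923131 to 82924948 (fold 7.72), chromosome X at 35231592 to 35232065 (fold 7.65), chromosome 11 at 87660841 to 87661736 and chromosome 14 at 98903309 to 98904075 (both fold 7.57).

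**Figure D3:**
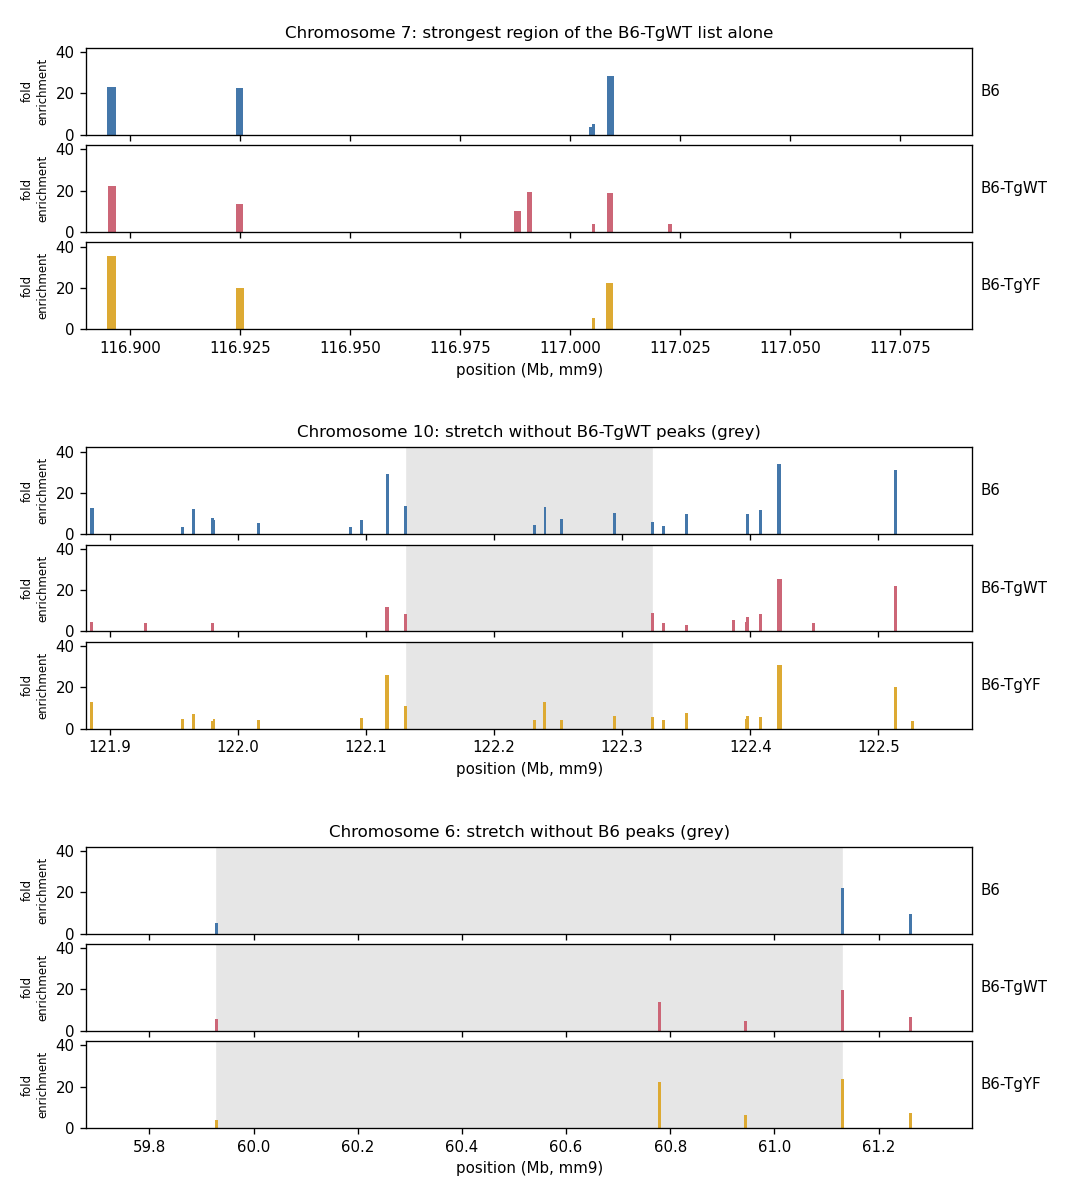
Peaks of each list in 3 windows, with position in Mb of mm9 on the x axis and the authors' fold enrichment as bar height on the y axis; narrow peaks are drawn at a minimum width, and grey marks the stretch between neighbouring peaks of the list named. On chromosome 7 the peak of fold 19.45 stands in the B6-TgWT list alone, on chromosome 10 the stretch from 122131849 to 122323042 holds 4 regions of B6 and B6-TgYF, and on chromosome 6 the stretch from 59929061 to 61129346 holds 2 regions of both transgenic lists and no B6 peak. The chromosome 10 stretch ranked first of 526 runs of 2 or more such regions, by region count and then summed fold. Absence from the B6-TgWT list does not show a loss of sites there.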

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

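Chromosome Y was left out of the comparisons, and its peaks are listed for that reason: 6 in the B6 list, 6 in the B6-TgWT list and 5 in the B6-TgYF list.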

How the results depend on the processing

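Of 133 alternatives over 22 results, 85 left the value within its interval or within 1.5 times its count and 48 did not. The floor of −log10 p and the removal of the start of chromosome 11 were chosen after the data were seen. The cause was not tested for the overlap rules or the −log10 q ranking; the strength and length settings remove peaks by construction. No paired analysis was possible because each line has 1 list for both replicates, so leaving out replicates was not run either. Promoter windows, gene lists and motif windows were not run, as no mm9 annotation or sequence was used here. Unknown depth limits all calls of absence.

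With summits within 500 bp, 71.6% of B6 peaks were matched in B6-TgWT and 79.1% in B6-TgYF, 17.6% were absent from both, and 8.26% of B6-TgWT peaks absent from B6 were matched in B6-TgYF. B6-TgYF regions absent from B6 were then 1861, with 1090 in B6-TgYF alone and 771 in both transgenic lists. Extending peaks by 500 bp gave 76.3%, 83.0% and, absent from both, 14.5%.

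Keeping the strongest 50% of each list left 25579, 23875 and 21255 peaks, B6 overlaps of 78.7% (B6-TgWT) and 79.7% (B6-TgYF), 14.7% absent from both and 9.335% of B6-TgWT peaks absent from B6 overlapped in B6-TgYF. Regions were 3274 in B6-TgWT and not B6, 3768 in B6 alone, 2972 in B6-TgWT alone, 1670 in B6 and B6-TgYF, 302 in both transgenic lists and 18677 in all 3.

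With the strongest 50% of the list asked about against the other lists in full, the overlaps were 99.6% and 99.9%, 0% were absent from both and 0.4175% were overlapped in B6-TgYF. Regions were 2394 in B6-TgWT and 1 in B6-TgYF without B6, 0 in B6 alone, 2385 in B6-TgWT alone, 0 in B6-TgYF alone, 66 in B6 and B6-TgWT, 104 in B6 and B6-TgYF, and 9 in both transgenic lists. The median width of the 2385 peaks of B6-TgWT alone was 1710 bp.

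With lists of equal length the overlaps were 77.4% and 90.5%, 8.19% were absent from both and 8.0755% were overlapped in B6-TgYF. Regions were 3050 in B6-TgYF and not B6, 3482 in B6 alone, 2370 in B6-TgYF alone, 537 in B6 and B6-TgWT, and 680 in both transgenic lists. A common floor of −log10 p moved the B6 overlap in B6-TgWT to 73.7%. Ranking by −log10 q moved the median percentile to 10.8 for B6 alone and 5.07 for B6-TgYF alone.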

Other observations

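The tests of the regions gained in B6-TgWT and of the chromosome 6 stretch were chosen after their results were seen. The bounds for B6 sites absent from the transgenic lists were set before, but the −log10 q version of that test and the rule that both versions must agree were added after the fold version had given its value.

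Chromosome X held 1.36% of the regions of the B6-TgWT list alone (interval 1.14 to 1.62), 2.24% of the regions of all 3 lists and 2.79% of those of the B6 list alone (interval 2.46 to 3.15). The B6-TgYF list alone had 1.32% on X, with a wide interval of 0.606 to 2.85 over its 455 regions, B6 and B6-TgYF without B6-TgWT had 1.67%, and B6 and B6-TgWT without B6-TgYF had 1.96%. In the B6-TgYF list, 21 of its 455 own regions (4.62%) lay within 69.3 kb at the start of chromosome 11, from 3030711 to 3100014, with fold enrichments of 1.41 to 1.83. The same stretch held 24 peaks of the B6-TgYF list, 3 of the B6 list and 2 of the B6-TgWT list. The 21 regions were noticed in a scan of 500 kb windows.

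A pattern to follow up is the set of 9123 regions in the B6-TgWT list and not in B6. Peaks near the list's cutoff cannot be the whole cause, since 26.3% of the peaks of that list alone lay in its stronger 50%, though single weak peaks may be of that kind. Fragments split from neighbouring peaks are argued against by the 4.05% of the regions of that list alone within 1 kb of a region of all 3 lists, against 10.01% among the latter themselves. A difference of both transgenic lines from the B6 list, in substrain or age, would, as the whole cause, put over 50% of the sites in B6-TgYF. With the B6 list in full, B6-TgYF overlapped 0.80% of the 9126 B6-TgWT peaks absent from B6, and 0.4175% of the 2395 stronger ones. Other settings redefined absence from B6, so their sets can include peaks that overlap the full B6 list. The shares were then 8.0755% of 8532 with equal lengths, 8.26% of 11036 with summits within 500 bp and 9.335% of 3278 with the strongest 50% of each list. In the last set the interval of 8.39 to 10.4 passes the 10% set as the limit for this test. Left open are H3K4me3 placed by the PRDM9 of the WT transgene, as a hypothesis, and anything else that sets the B6-TgWT line, substrain or libraries apart, because there was 1 line and 1 list of each kind; the hypothesis was not tested, which would need the sequence under these regions or the DMC1 libraries, neither used here.

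B6 sites were absent from the B6-TgWT list more often than from the B6-TgYF list. The higher lowest −log10 p of the B6-TgWT list is not enough, as the ratio was 3.14 with a common floor. Lower sensitivity of the B6-TgWT libraries at every site may be the cause and cannot be told apart from a loss at particular sites. At the 35780 regions of all 3 lists, the median fold enrichment was 11.77 in B6, 8.26 in B6-TgWT and 9.3 in B6-TgYF. It was lowest in B6-TgWT, although folds of separate lists show no change by themselves. With the B6-TgYF list limited by fold enrichment to as many B6 peaks as B6-TgWT overlapped, the ratio of stronger B6 peaks absent from B6-TgWT to those absent from B6-TgYF was 0.529 (0.416 to 0.662), under the bound of 1.5 set for lower sensitivity, and in the upper 60% of B6 peaks 721 were absent from B6-TgWT against 889. Limited by −log10 q, the ratio was 1.44 with an interval of 1.08 to 1.94 that spans the bound. Both intervals come from 10000 Poisson redraws of the absent peaks. The fold and −log10 q versions gave opposite directions, so the outcome depended on how the list was limited, and the test cannot decide. The explanation stays open, and the ratio of 3.79 is not to be read as sites lost with the WT transgene.

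A stretch of chromosome 6 from 59929061 to 61129346 had no B6 peak and 2 regions of both transgenic lists. Those lists had peaks in it only from 60778189 to 60944981. The stretch was the 1 run of 2 or more such regions among 69 B6 stretches, while the B6-TgWT list had 526 such runs among 4447 and the B6-TgYF list 57 among 1269. The number of regions that could form runs differed too, with 70 for B6, 5043 for B6-TgWT and 1329 for B6-TgYF. Being the only run therefore does not mark the stretch as unusual. For the stronger region, a site too weak to be called in B6 is argued against by its percentile, 82.1 of the B6-TgYF list and 74.8 of the B6-TgWT list. The other region lay only at percentile 40.1 of the B6-TgYF list and 23.0 of the B6-TgWT list. A weak site stays open for that region, and the run of 2 rests on it. A deletion in the B6 substrain is a candidate explanation, since C57BL/6JOlaHsd is known to carry one on chromosome 6, but whether this is that segment was not checked. With 2 regions in a stretch chosen for lacking B6 peaks, the lists cannot decide it, and the coverage of the B6 input, not used here, would.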
